A study of Homo sapiens with 10 samples.

How the data were processed

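RNA from UM-Chor1 chordoma cells was sequenced in 10 libraries. By the labels, 750000 cells per dish were seeded on collagen I in IMDM and RPMI medium with serum and given DMSO, THZ1 (100 or 500 nM) or actinomycin D (10 or 150 ng/mL) the next day, with harvest after 4 h. RNA was taken with an RNeasy kit, and stranded mRNA libraries were read as single-end 75 bp reads on a NextSeq 500. The submitters' processing notes name Trim Galore 0.4.1, STAR 2.4.2 and the GRCh38 build. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts of reads per Ensembl gene, as whole numbers for 60498 genes in 1 column per library, with 4 further entries for reads that were ambiguous, multimapping, outside genes or unmapped. These entries held 18.7% to 31.6% of the reads of a library and were left out of all gene tests. All 10 columns were matched to a sample, and 0 were left unmapped.

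Gene symbols, positions, span and exon length came from GENCODE release 29, which matched 56868 identifiers without their version, 51657 of them with it. The other 3630 kept their identifier and held at most 0.0220% of a library's gene counts. Reads assigned to genes ranged from 32577762 to 53829486 per library, and the biological coefficient of variation was 0.0345. The 5 groups follow the labels, with 2 biological replicates each.

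Counts were filtered with filterByExpr, which left 17871 genes, scaled with TMM factors and fitted in 1 model of group means over all 10 libraries with 5 residual degrees of freedom, using robust quasi-likelihood F tests in edgeR 4.0.16 in R 4.3.3. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with adjustment over the tested genes of each comparison. The 8 comparisons were each compound dose against DMSO, the 2 doses of each compound, and the 2 compounds at the lower and at the higher doses. SE and 95% intervals come from the fitted coefficients and their tests. CPM values use the TMM-scaled library sizes. The 28 gene lists were written from general knowledge, tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over all lists and comparisons together, and repeated with a correlation estimated per list. Genes were named from the lists (up to 4 per list, by adjusted p and at any level), from those changed most with at least 10 CPM in 1 of the 2 groups (without pseudogenes and genes that carry only a clone or database name), or because they were fixed in advance as the target, the markers or the inhibited kinases. The lists, groups, comparisons, tests and most alternatives were chosen before the data were examined.

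The calls were tested on simulated data, with counts drawn at the DMSO means with the fitted dispersions (16698 genes tested). In the THZ1 500 nM group, 200 changed genes were planted. A further 30 p53 target genes were raised 1.5-fold there and were not counted as false calls. With edgeR, 89.6% of genes changed 1.5-fold were recovered, 97.0% of those changed 2-fold and 100% of those changed 4-fold, and 5.56% of calls were false. False calls were 2.74% with DESeq2 and 9.05% with limma-voom. With so few changed genes, these values do not test the scaling or the calls where most genes change. In THZ1 500 nM against DMSO, 67.5% of genes passed. Correlations between 2 comparisons with the same DMSO libraries were set against 20 simulations of unchanged groups.

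Alternatives were DESeq2's size factors, upper-quartile factors, library totals and the 13 mitochondrially encoded protein genes for scaling, other count filters, DESeq2 1.42.0, limma-voom, a fit of only the 4 libraries compared, a replicate block, an adjusted p under 0.01, a fold change of at least 2, and each library left out in turn. Leaving out the mitochondrial genes and removing each library's trend of log2 CPM with transcript GC content were added after the data were seen. Relations to gene span and GC content used 11555 protein-coding genes at 1 CPM or more in DMSO and Spearman correlations, and neighbouring genes were compared with 10000 draws matched on DMSO expression in 20 classes, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Splicing, variants and reads outside annotated genes were not analysed here.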

Results

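Gene expression was measured in UM-Chor1, an established human chordoma cell line, 4 h after vehicle or compound was added. THZ1 covalently inhibits the transcriptional kinase CDK7, and also CDK12 and CDK13. Actinomycin D binds DNA, blocks RNA polymerase I at low doses and blocks RNA polymerase II as well at higher doses. The 10 libraries formed 5 groups of 2 biological replicates: DMSO, THZ1 at 100 nM, THZ1 at 500 nM, actinomycin D at 10 ng/mL and actinomycin D at 150 ng/mL. Reads assigned to genes ranged from 32577762 to 53829486 per library. Of 17871 genes tested, 8877 averaged at least 10 CPM over the libraries. Across these 8877 genes, the first principal component held 81.3% of the variance and the second 14.1%. On the first, DMSO and THZ1 100 nM libraries lay between -34.3 and -32.8, actinomycin D 10 ng/mL at -21.1 and -21.0, THZ1 500 nM at 28.3 in both libraries, and actinomycin D 150 ng/mL at 58.3 and 61.6.

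Changes are log2 fold changes ± SE with 2 libraries per group, tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and are relative to the median gene, since bulk counts carry no measure of RNA per cell. Scaling on the 13 mitochondrially encoded protein genes moved the median of all genes against DMSO to -0.34 for THZ1 100 nM, -0.84 for THZ1 500 nM, -0.18 for actinomycin D 10 ng/mL and -0.98 for actinomycin D 150 ng/mL. That scale is itself loose, as the share of counts from these 13 genes was 2.38% and 3.55% in the DMSO libraries. Upper-quartile scaling moved the median to 0.27 for THZ1 500 nM, 0.11 for actinomycin D 10 ng/mL and 0.43 for actinomycin D 150 ng/mL, and scaling by library totals moved it to -0.12 for THZ1 500 nM and -0.21 for actinomycin D 150 ng/mL. Removal of each library's trend with GC content moved it to 0.15 for THZ1 500 nM and 0.25 for actinomycin D 150 ng/mL. Where a scaling changed the sign of a list's median, that median is given as well, except for these 13 genes under their own scaling, which sets their median close to 0. List medians were not computed with the GC trend removed.

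The series concerns dependence of chordoma on brachyury, the T-box transcription factor of the notochord encoded by TBXT (ENSG00000164458.9, chromosome 6, 166157656 to 166168700, GRCh38). Brachyury mRNA was at 1040 ± 9.44 CPM (SD, n = 2) in DMSO, and THZ1 at 500 nM lowered it to 522 ± 5.63 CPM, a fall of 49.8% (log2 fold change -0.99 ± 0.04, 95% CI -1.08 to -0.91, edgeR adjusted p = 6.7e-18, and -0.70 under upper-quartile and -1.80 under mitochondrial scaling). Actinomycin D at 150 ng/mL lowered it to 725 ± 1.67 CPM, a fall of 30.3% (-0.52 ± 0.04, edgeR adjusted p = 4.6e-12, and -0.11 under upper-quartile and -1.51 under mitochondrial scaling). These alternatives passed too, but the size of the falls depends on the scale. At the lower doses brachyury was at 939 ± 26.2 CPM with THZ1 (-0.15 ± 0.04, 95% CI -0.23 to -0.06, edgeR adjusted p = 0.065) and at 1053 ± 20.3 CPM with actinomycin D (0.02 ± 0.04, edgeR adjusted p = 0.76), and neither difference passed. The value for THZ1 100 nM passed under 7 of the other analyses tried, with log2 fold changes from -0.23 to -0.14. The value for actinomycin D 10 ng/mL passed under upper-quartile scaling alone (0.11) and was -0.03 with the GC trend removed. Under mitochondrial scaling the 2 values were -0.49 and -0.17, without passing.

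Brachyury fell between the doses of THZ1 (-0.85 ± 0.04, edgeR adjusted p = 2.0e-16, and -0.54 under upper-quartile and -1.31 under mitochondrial scaling) and between the doses of actinomycin D (-0.54 ± 0.04, edgeR adjusted p = 2.9e-12, and -0.22 and -1.34 under the same scalings). It was lower in THZ1 500 nM than in actinomycin D 150 ng/mL (-0.47 ± 0.04, edgeR adjusted p = 1.2e-10, and -0.29 without passing under mitochondrial scaling). It was also lower in THZ1 100 nM than in actinomycin D 10 ng/mL (-0.17 ± 0.04, edgeR adjusted p = 0.0020, and -0.27 under upper-quartile scaling), a call that was lost without THZ1 100 nM replicate 2 (-0.13), without actinomycin D 10 ng/mL replicate 1 (-0.15) and under mitochondrial scaling (-0.32). In THZ1 500 nM, 15.3% of all tested genes had a lower fold change than TBXT, and 4.70% of the 1788 genes in the top 10% by expression. The same shares for actinomycin D 150 ng/mL were 32.1% and 16.4%.

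**Figure D1:**
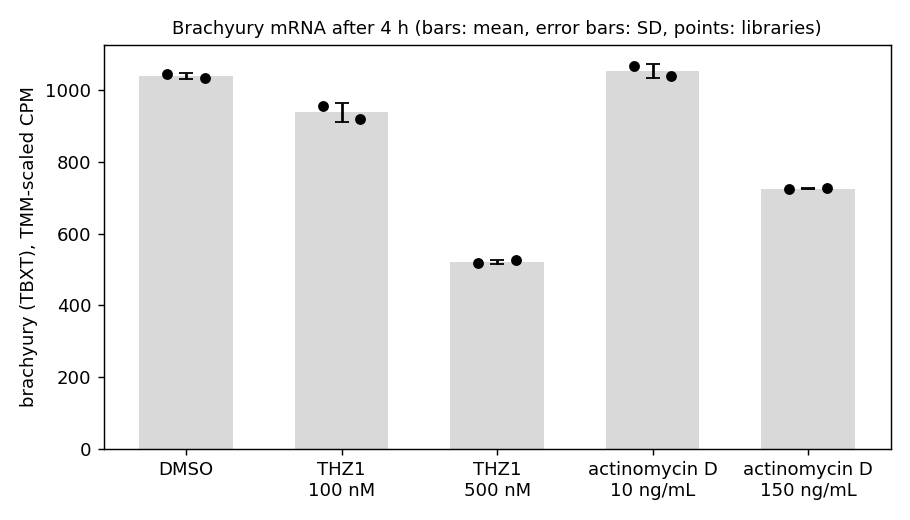
Brachyury (TBXT) mRNA in CPM by group, with bars for the mean, error bars for the SD and points for the 2 libraries of each group. Group means were 1040 in DMSO, 522 in THZ1 500 nM and 725 in actinomycin D 150 ng/mL.

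The comparison of THZ1 500 nM with DMSO asks which transcripts change within 4 h of the higher dose, without separating the kinases that THZ1 inhibits. The notochord and chondrocyte transcription factor SOX9 (-1.53 ± 0.04) fell, and KRT19 (-1.47 ± 0.05) and FOXA1 (-1.81 ± 0.07), a keratin of simple epithelia and a pioneer factor, fell with it. These genes are on the list of notochord and chordoma markers, most of which rose, as given below. The anti-apoptotic gene MCL1 (-1.17 ± 0.04), the cell-cycle inhibitor CDKN1A (-1.06 ± 0.05), the p53 ubiquitin ligase MDM2 (-1.21 ± 0.05) and the growth regulator MYC (-0.46 ± 0.05) all fell. So did the targets of the compound, CDK7 (-1.18 ± 0.06), CDK12 (-1.25 ± 0.05) and CDK13 (-0.82 ± 0.05). The AP-1 gene FOS (1.09 ± 0.14), the P-TEFb inhibitor HEXIM1 (0.47 ± 0.05) and the largest RNA polymerase II subunit POLR2A (1.17 ± 0.05) rose, and the AP-1 gene JUN (-0.55 ± 0.10) fell, while HEXIM1 changed sign under mitochondrial scaling. JUN did not pass under upper-quartile scaling (-0.26) or in the fit of the 4 libraries (-0.49). Under mitochondrial scaling FOS (0.29) and POLR2A (0.36) did not pass. In all, 5378 genes rose and 6684 fell, 1355 and 2606 of them by at least 2-fold, a split that was 8232 and 4714 under upper-quartile scaling, 581 and 10655 under mitochondrial scaling and 7157 and 5492 under removal of the GC trend.

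Among genes with at least 10 CPM in 1 of the 2 groups, without pseudogenes and those with only a clone or database name, the largest falls were in PPP1R10 (-3.55 ± 0.08), a nuclear subunit of protein phosphatase 1, GTF2E1 (-3.50 ± 0.12), a subunit of the general factor TFIIE, DCLRE1B (-3.47 ± 0.10), a telomere nuclease, ZNF225 (-3.17 ± 0.10), E2F8 (-3.14 ± 0.11), a cell-cycle repressor, and KRCC1 (-3.12 ± 0.10). The largest rises by the same rule, which holds for each comparison, were in FAM166A (6.19 ± 0.21), MGC12916 (3.24 ± 0.08), KRT15 (2.83 ± 0.07), BEST1 (2.80 ± 0.14), JUNB (2.59 ± 0.14) and IER5L (2.47 ± 0.08). FAM166A, BEST1 and JUNB overlap TUBB4B, FTH1 and HOOK2 on the other strand, and the strand setting of the counting is not given in the sources used here, so these 3 rises are uncertain. On 1 strand, KRT15 begins 1088 bp past the end of KRT19, which averaged 3936 CPM in DMSO, so its rise may hold reads that run on from KRT19.

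Of 31 p53 target genes, 26 fell, such as AEN (-2.43 ± 0.05), PLK2 (-1.74 ± 0.05) and PHLDA3 (-1.56 ± 0.05), and 2 rose (26 and 2 adjusted over the list alone). Their median was -0.81, camera adjusted p = 6.8e-09 and adjusted p = 0.16 with an estimated correlation. Of 30 mitosis genes, 26 fell, such as AURKA (-2.04 ± 0.05), TTK (-1.73 ± 0.06), AURKB (-1.96 ± 0.07) and CENPA (-2.12 ± 0.08), and 1 rose (26 and 1 adjusted over the list alone). Their median was -0.64, camera adjusted p = 1.0e-09 and adjusted p = 0.26 with an estimated correlation. Among 18 YAP and TEAD target genes, 14 fell, such as AMOTL2 (-2.20 ± 0.05), CTGF (-1.74 ± 0.05) and CYR61 (-1.77 ± 0.05), and 3 rose (14 and 3 adjusted over the list alone). Their median was -0.91, camera adjusted p = 1.6e-09 and adjusted p = 0.038 with an estimated correlation. Of 33 ribosome biogenesis genes, 28 fell, such as WDR43 (-1.90 ± 0.05), NIFK (-1.86 ± 0.06) and BYSL (-1.88 ± 0.06), and 2 rose (28 and 2 adjusted over the list alone). Their median was -0.97, camera adjusted p = 1.4e-12 and adjusted p = 0.054 with an estimated correlation. Among 17 NF-kB early response genes, 14 fell, such as CXCL1 (-2.21 ± 0.05) and CXCL8 (-2.29 ± 0.07), and 1 rose (14 and 2 adjusted over the list alone). Their median was -1.07, camera adjusted p = 2.6e-07 and adjusted p = 0.11 with an estimated correlation. Among 29 immediate-early genes, 17 fell, such as FOSL1 (-2.23 ± 0.05) and KLF6 (-1.99 ± 0.05), and 9 rose (17 and 9 adjusted over the list alone). Their median was -0.55, camera adjusted p = 0.018 and adjusted p = 0.58 with an estimated correlation. Of 420 ZNF zinc finger genes (many with close paralogs), 316 fell, such as ZNF146 (-2.43 ± 0.05) and ZNF672 (-2.34 ± 0.06), and 25 rose (319 and 26 adjusted over the list alone). Their median was -1.10, camera adjusted p = 1.0e-15 and adjusted p = 0.18 with an estimated correlation. Among 21 receptor tyrosine kinase and ERK feedback genes, 16 fell, such as DUSP4 (-1.53 ± 0.04) and SPRY2 (-1.89 ± 0.09), and 3 rose (16 and 3 adjusted over the list alone). Their median was -0.47, camera adjusted p = 1.2e-04 and adjusted p = 0.26 with an estimated correlation.

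Of 81 ribosomal protein genes, 77 rose, such as RPL12 (0.55 ± 0.05), RPL37 (0.59 ± 0.05) and RPS2 (0.59 ± 0.05), and 3 fell (77 and 3 adjusted over the list alone). Their median was 0.47 and -0.34 under mitochondrial scaling, camera adjusted p = 4.4e-13 and adjusted p = 0.58 with an estimated correlation. Among 81 nuclear-encoded respiratory chain genes, 73 rose, such as NDUFB7 (0.56 ± 0.05) and ATP5F1B (0.48 ± 0.05), and 1 fell (73 and 1 adjusted over the list alone). Their median was 0.40 and -0.39 under mitochondrial scaling, camera adjusted p = 8.2e-10 and adjusted p = 0.56 with an estimated correlation. Among 17 glycolysis genes, 14 rose, such as PKM (0.54 ± 0.05) and GAPDH (0.57 ± 0.05), and 1 fell (14 and 1 adjusted over the list alone). Their median was 0.46 and -0.35 under mitochondrial scaling, camera adjusted p = 5.0e-04 and adjusted p = 0.62 with an estimated correlation. Among 28 extracellular matrix genes, 17 rose, such as TIMP1 (0.69 ± 0.05) and TIMP2 (0.62 ± 0.04), and 5 fell, such as THBS1 (-1.72 ± 0.04) (17 and 5 adjusted over the list alone). Their median was 0.34 and -0.48 under mitochondrial scaling, camera adjusted p = 0.013 and adjusted p = 0.41 with an estimated correlation. Among 13 mitochondrially encoded protein genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone). Their median was 0.73, camera adjusted p = 0.046 and adjusted p = 0.76 with an estimated correlation. Among 18 replication-dependent histone genes (near-identical copies whose mRNAs mostly lack poly(A) tails, with the 2 named here under 3 CPM), 11 rose, such as HIST1H3G (4.20 ± 0.34) and HIST1H2AG (3.01 ± 0.26), and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.91, camera adjusted p = 0.013 and adjusted p = 0.32 with an estimated correlation. Among 23 notochord and chordoma markers, 15 rose and 7 fell (15 and 7 adjusted over the list alone). Their median was 0.23 and -0.59 under mitochondrial scaling, camera adjusted p = 0.24.

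Of 19 apoptosis regulators, 11 fell, such as BCL2L1 (-1.15 ± 0.04) and XIAP (-1.25 ± 0.07), and 2 rose (11 and 2 adjusted over the list alone). Their median was -0.54, camera adjusted p = 0.037 and adjusted p = 0.26 with an estimated correlation. Among 38 transcription-cycle kinases and elongation regulators, 25 fell, such as MEPCE (-1.69 ± 0.07), and 7 rose (25 and 7 adjusted over the list alone). Their median was -0.32, camera adjusted p = 0.028 and adjusted p = 0.48 with an estimated correlation. Among 28 DNA damage repair genes, 21 fell, such as BLM (-1.83 ± 0.08) and PALB2 (-2.65 ± 0.12), and 4 rose (21 and 4 adjusted over the list alone). Their median was -0.41, camera adjusted p = 0.034 and adjusted p = 0.59 with an estimated correlation. The 28 include BACH1, a transcription factor gene and not a repair gene, which is therefore in the counts and tests of this list in each comparison. Among 31 DNA replication genes, 16 fell and 8 rose (16 and 8 adjusted over the list alone). Their median was -0.20 and 0.10 under upper-quartile scaling, camera adjusted p = 0.011 and adjusted p = 0.64 with an estimated correlation. Among 20 heat shock chaperones, 15 fell, such as DNAJB1 (-1.70 ± 0.05), and 4 rose (15 and 4 adjusted over the list alone). Their median was -0.37, camera adjusted p = 0.042 and adjusted p = 0.70 with an estimated correlation. Among 22 unfolded protein and integrated stress response genes, 12 fell, such as XBP1 (-2.30 ± 0.07) and HERPUD1 (-1.82 ± 0.07), and 6 rose (12 and 6 adjusted over the list alone). Their median was -0.62, camera adjusted p = 0.046 and adjusted p = 0.64 with an estimated correlation. Among 27 splicing factor and CLK genes, 17 fell, such as SRSF3 (-1.48 ± 0.05), and 2 rose (17 and 2 adjusted over the list alone). Their median was -0.23 and 0.07 under upper-quartile scaling, camera adjusted p = 0.0037 and adjusted p = 0.32 with an estimated correlation. Among 17 TGF-beta and BMP target genes, 11 fell, such as ID3 (-1.84 ± 0.06) and PMEPA1 (-1.48 ± 0.04), and 5 rose (11 and 5 adjusted over the list alone). Their median was -0.70, camera adjusted p = 0.065.

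Few markers of other cell types were tested. Among fibroblast markers 4 of 8 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.04, mean -0.11 and camera direction up, -0.04 under scaling by library totals and -0.76 under mitochondrial scaling, camera adjusted p = 0.52), among endothelial markers 3 of 6 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.46, -0.33 under mitochondrial scaling, camera adjusted p = 0.30), and among blood cell markers 1 of 3 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.78, -0.04 under mitochondrial scaling, camera adjusted p = 0.52). THY1 (0.57 ± 0.05) and EGFL7 (0.63 ± 0.06), markers of fibroblasts and endothelium, rose, and both changed sign under mitochondrial scaling. Cholesterol synthesis genes went both ways, as 9 of 23 rose and 10 fell (9 and 10 adjusted over the list alone, median -0.001, 0.04 under DESeq2's size factors and 0.30 under upper-quartile scaling, camera adjusted p = 0.70), and among snoRNA host genes 3 of 20 rose and 12 fell (4 and 12 adjusted over the list alone, median -0.48, camera adjusted p = 0.18).

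Actinomycin D at 150 ng/mL against DMSO shared part of the changes seen with THZ1 500 nM. The notochord factor SOX9 (-2.74 ± 0.05), the keratin KRT19 (-1.66 ± 0.05), the growth regulator MYC (-1.45 ± 0.06), the p53 ligase MDM2 (-1.53 ± 0.05), the anti-apoptotic MCL1 (-0.63 ± 0.04) and the cell-cycle inhibitor CDKN1A (-0.73 ± 0.05) fell. The kinase genes CDK7 (-2.28 ± 0.07), CDK12 (-2.38 ± 0.06) and CDK13 (-2.42 ± 0.06) fell too. Among 23 notochord and chordoma markers, 15 rose and 6 fell (15 and 6 adjusted over the list alone). Their median was 0.46 beside a mean of -0.01 and a camera direction of up, with -0.54 under mitochondrial scaling, camera adjusted p = 0.30. The AP-1 genes FOS (1.33 ± 0.14) and JUN (1.07 ± 0.10) and HEXIM1 (0.58 ± 0.05) rose, of which HEXIM1 changed sign under mitochondrial scaling. Immediate-early genes went both ways, since MYC, which fell, is on that list with FOS and JUN. Under mitochondrial scaling FOS (0.33) and JUN (0.09) did not pass. In all, 6081 genes rose and 6735 fell, 1587 and 3530 by at least 2-fold, a split that was 9016 and 4772 under upper-quartile scaling, 4409 and 7950 under scaling by library totals, 306 and 11096 under mitochondrial scaling and 7816 and 5447 under removal of the GC trend.

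The largest falls were in SPSB1 (-4.72 ± 0.10), RNF144B (-4.40 ± 0.08), BMT2 (-4.34 ± 0.13), IRF2 (-4.33 ± 0.16), LRIG3 (-4.11 ± 0.10) and SH3RF1 (-4.08 ± 0.14), of which RNF144B encodes a ubiquitin ligase and IRF2 an interferon-related transcription factor. The largest rises were in C11orf96 (2.63 ± 0.15), MT-RNR1 (2.35 ± 0.17), MT-RNR2 (2.18 ± 0.21), SHH (2.13 ± 0.07), IER2 (2.05 ± 0.08) and TLCD2 (1.96 ± 0.13). MT-RNR1 and MT-RNR2 are the mitochondrial ribosomal RNAs, SHH is the morphogen secreted by the notochord, and IER2 is an immediate-early gene. Of 31 p53 target genes, 23 fell, such as PLK2 (-2.62 ± 0.05), PPM1D (-3.15 ± 0.08) and AEN (-1.69 ± 0.05), and 7 rose (23 and 7 adjusted over the list alone). Their median was -0.79, camera adjusted p = 2.2e-05 and adjusted p = 0.18 with an estimated correlation. Among 18 YAP and TEAD target genes, 14 fell, such as CTGF (-3.62 ± 0.05), CYR61 (-3.93 ± 0.06) and AMOTL2 (-3.36 ± 0.05), and 3 rose (14 and 3 adjusted over the list alone). Their median was -1.27, camera adjusted p = 1.1e-10 and adjusted p = 0.052 with an estimated correlation. Among 17 TGF-beta and BMP target genes, 11 fell, such as PMEPA1 (-3.68 ± 0.05), SKI (-3.76 ± 0.06) and ID3 (-3.06 ± 0.07), and 3 rose (11 and 3 adjusted over the list alone). Their median was -0.88, camera adjusted p = 1.4e-04 and adjusted p = 0.26 with an estimated correlation. Of 33 ribosome biogenesis genes, 27 fell, such as WDR43 (-3.46 ± 0.06), UTP15 (-2.51 ± 0.07) and POLR1B (-2.08 ± 0.06), and 5 rose (27 and 5 adjusted over the list alone). Their median was -0.92, camera adjusted p = 7.0e-08 and adjusted p = 0.13 with an estimated correlation. Among 38 transcription-cycle kinases and elongation regulators, 26 fell, such as AFF4 (-2.29 ± 0.06), and 7 rose (26 and 7 adjusted over the list alone). Their median was -0.76, camera adjusted p = 4.6e-06 and adjusted p = 0.26 with an estimated correlation. Among 17 NF-kB early response genes, 13 fell, such as CXCL1 (-3.50 ± 0.05) and NFKB1 (-2.63 ± 0.08), and 2 rose (13 and 2 adjusted over the list alone). Their median was -1.33, camera adjusted p = 2.9e-05 and adjusted p = 0.21 with an estimated correlation.

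Of 81 ribosomal protein genes, 78 rose, such as RPL12 (0.95 ± 0.05) and RPL37 (0.99 ± 0.05), and 2 fell (78 and 2 adjusted over the list alone). Their median was 0.76 and -0.24 under mitochondrial scaling, camera adjusted p = 6.3e-18 and adjusted p = 0.50 with an estimated correlation. Among 81 nuclear-encoded respiratory chain genes, 73 rose, such as NDUFV1 (0.85 ± 0.05) and COX4I1 (0.82 ± 0.05), and 0 fell (74 and 0 adjusted over the list alone). Their median was 0.68 and -0.32 under mitochondrial scaling, camera adjusted p = 2.2e-13 and adjusted p = 0.49 with an estimated correlation. Among 13 mitochondrially encoded protein genes, 9 rose, such as MT-ND1 (1.57 ± 0.25), and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.78, camera adjusted p = 0.11. Of 420 ZNF zinc finger genes, 316 fell, such as ZNF146 (-2.62 ± 0.05) and ZNF609 (-2.85 ± 0.07), and 31 rose (320 and 32 adjusted over the list alone). Their median was -1.05, camera adjusted p = 2.0e-08 and adjusted p = 0.32 with an estimated correlation. Among 30 mitosis genes, 25 fell, such as TTK (-2.81 ± 0.06) and KIF11 (-1.51 ± 0.05), and 2 rose (26 and 2 adjusted over the list alone). Their median was -0.72, camera adjusted p = 2.2e-05 and adjusted p = 0.38 with an estimated correlation. Among 19 apoptosis regulators, 11 fell, such as BCL2L1 (-2.25 ± 0.05) and BCL2 (-1.83 ± 0.11), and 6 rose, such as PMAIP1 (1.30 ± 0.08) (11 and 6 adjusted over the list alone). Their median was -0.56, camera adjusted p = 0.24. Under mitochondrial scaling PMAIP1 (0.31) did not pass. Among 20 snoRNA host genes, 13 rose, such as SNHG1 (0.53 ± 0.04), and 5 fell, such as SNHG17 (-1.65 ± 0.07) (13 and 5 adjusted over the list alone). Their median was 0.41 and -0.58 under mitochondrial scaling, camera adjusted p = 0.13. Among 23 cholesterol synthesis genes, 10 fell, such as SQLE (-1.40 ± 0.05), and 9 rose (10 and 9 adjusted over the list alone). Their median was 0.02 beside a mean of -0.14 and a camera direction of up, with medians of -0.20 under scaling by library totals and -0.96 under mitochondrial scaling, camera adjusted p = 0.87.

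Actinomycin D at 10 ng/mL against DMSO tests the low dose, at which the drug is known to act mainly on ribosomal RNA synthesis. The p53 target genes rose most clearly, led by the cell-cycle inhibitor CDKN1A (1.42 ± 0.05), the stress cytokine GDF15 (1.44 ± 0.08), the antiproliferative gene BTG2 (1.37 ± 0.06) and the p53 ligase MDM2 (0.70 ± 0.04). Of 31 p53 target genes, 25 rose, such as TP53INP1 (0.84 ± 0.05) and FDXR (0.92 ± 0.05), and 1 fell (27 and 1 adjusted over the list alone). Their median was 0.46, camera adjusted p = 4.4e-24 and adjusted p = 0.038 with an estimated correlation. The polymerase subunit POLR2A (1.46 ± 0.05) and the P-TEFb inhibitor HEXIM1 (0.90 ± 0.05) also rose, as did FOS (0.71 ± 0.15) and MCL1 (0.36 ± 0.04). The genes SOX9 (-0.39 ± 0.04) and KRT19 (-0.19 ± 0.04) and the kinase genes CDK12 (-0.35 ± 0.05) and CDK13 (-0.32 ± 0.05) fell. Among 23 notochord and chordoma markers, 8 rose and 4 fell (8 and 4 adjusted over the list alone). Their median was 0.04 and -0.14 under mitochondrial scaling, camera adjusted p = 0.48. MYC (0.01 ± 0.05) and JUN (0.22 ± 0.10) did not pass, although JUN passed without DMSO replicate 2 (0.36). CDK7 (-0.19 ± 0.05) passed, but not without DMSO replicate 1 (-0.17) or actinomycin D 10 ng/mL replicate 2 (-0.17), and it was 0.01 with the GC trend removed. KRT19 did not pass under upper-quartile scaling (-0.09). JUN passed under upper-quartile scaling (0.32), without the low-count filter (0.22), under limma-voom (0.23) and with the replicate block (0.22). CDK7 did not pass under upper-quartile scaling (-0.09). MDM2 (0.52), TP53INP1 (0.66), FDXR (0.74), HEXIM1 (0.72), FOS (0.50), MCL1 (0.18), SOX9 (-0.58), KRT19 (-0.37), CDK12 (-0.54), CDK13 (-0.51) and CDK7 (-0.38) did not pass under mitochondrial scaling.

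In all, 3281 genes rose and 3857 fell, 364 and 272 by at least 2-fold. The count of genes higher in actinomycin D 10 ng/mL than in DMSO was 2110 without DMSO replicate 1 and 2113 without actinomycin D 10 ng/mL replicate 1, and the split was 5240 and 2784 under upper-quartile scaling, 124 and 869 under mitochondrial scaling and 4583 and 2724 under removal of the GC trend. The largest falls were in LDLRAD4 (-2.54 ± 0.08), a brake on TGF-beta signalling, GLI2 (-2.04 ± 0.07), a Hedgehog transcription factor, HDAC4 (-1.84 ± 0.08), a histone deacetylase, and SH3RF3 (-1.90 ± 0.09), JAZF1 (-1.83 ± 0.08) and ZFPM2 (-1.82 ± 0.08). Outside the p53 targets, the largest rises were in MGC12916 (1.78 ± 0.10), KRT15 (1.65 ± 0.08) and DOK3 (1.55 ± 0.10), with KRT15 again next to KRT19. Of 20 heat shock chaperones, 16 rose, such as DNAJB1 (0.49 ± 0.04) and the near-identical copies HSPA1A (0.82 ± 0.06) and HSPA1B (0.97 ± 0.07), and 2 fell (16 and 2 adjusted over the list alone). Their median was 0.33, camera adjusted p = 1.3e-07 and adjusted p = 0.41 with an estimated correlation. Among 28 DNA damage repair genes, 21 fell, such as POLQ (-0.77 ± 0.06), WRN (-0.67 ± 0.06) and ATR (-0.57 ± 0.06), and 0 rose (23 and 0 adjusted over the list alone). Their median was -0.25, camera adjusted p = 3.1e-06 and adjusted p = 0.26 with an estimated correlation. Among 18 YAP and TEAD target genes, 13 fell, such as PTPN14 (-0.83 ± 0.05), TEAD1 (-0.67 ± 0.05) and CTGF (-0.58 ± 0.05), and 2 rose (14 and 2 adjusted over the list alone). Their median was -0.29, camera adjusted p = 1.2e-04 and adjusted p = 0.11 with an estimated correlation. Among 20 snoRNA host genes, 12 rose, such as SNHG1 (0.41 ± 0.04) and SNHG12 (0.57 ± 0.08), and 0 fell (13 and 0 adjusted over the list alone). Their median was 0.28, camera adjusted p = 3.4e-04 and adjusted p = 0.28 with an estimated correlation. Among 29 immediate-early genes, 14 rose, such as ATF3 (1.12 ± 0.07), and 2 fell (17 and 2 adjusted over the list alone). Their median was 0.24, camera adjusted p = 1.3e-05 and adjusted p = 0.36 with an estimated correlation. Among 33 ribosome biogenesis genes, 9 fell, such as HEATR1 (-0.51 ± 0.05) and POLR1A (-0.43 ± 0.05), and 6 rose (10 and 6 adjusted over the list alone). Their median was -0.03 and 0.07 under upper-quartile scaling, camera adjusted p = 0.75. DNAJB1 (0.32), HSPA1A (0.66), ATR (-0.75), CTGF (-0.75), SNHG1 (0.24), SNHG12 (0.38), HEATR1 (-0.70) and POLR1A (-0.61) did not pass under mitochondrial scaling.

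Changes at actinomycin D 10 ng/mL followed gene span. Across 11555 protein-coding genes, which are not independent replicates, the Spearman correlation of the change with annotated span was -0.65, and -0.66 and -0.63 for the 2 libraries taken singly. Between the 2 DMSO libraries it was 0.11. Of 863 genes under 5 kb, 49.4% rose and 3.48% fell, whereas of 909 genes over 200 kb, 1.76% rose and 80.6% fell. The gene list tests did not take span into account, so the list changes at this dose cannot be told apart from this trend. The repair genes POLQ, WRN and ATR span 100 to 200 kb, a class in which 71.5% fell (median -0.34). PTPN14 and TEAD1 span over 200 kb, while CTGF, under 5 kb, fell too. The correlation with span was -0.28 for actinomycin D 150 ng/mL, -0.22 for THZ1 100 nM and 0.0047 for THZ1 500 nM. The last value hides a relation that changed direction, as the median in THZ1 500 nM was 0.01 under 5 kb, -0.24 at 50 to 100 kb and -0.03 over 200 kb. Given GC content the correlation was -0.58 for actinomycin D 10 ng/mL, -0.20 for actinomycin D 150 ng/mL, -0.02 for THZ1 100 nM and 0.07 for THZ1 500 nM.

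**Figure D2:**
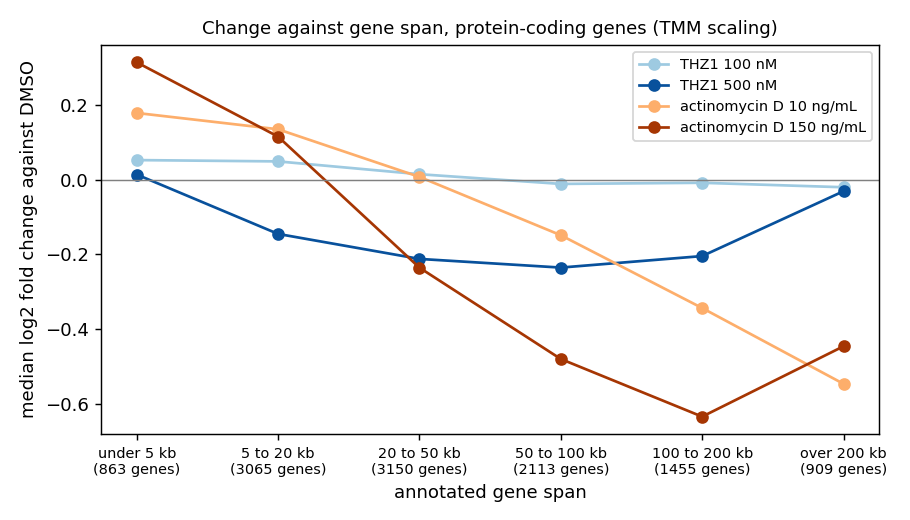
Median log2 fold change against DMSO, by class of annotated gene span in kb, with 1 line per treatment. Scaling shifts each line as a whole, and for actinomycin D 10 ng/mL the median goes from 0.18 under 5 kb to -0.55 over 200 kb.

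THZ1 at 100 nM against DMSO gave small changes. By the rule used for each comparison, the largest rises were in NR1D1, S100A1, ZFP36, RBM14, IRF7 and C15orf39. The largest falls were in PPP1R10, KRCC1, TUBD1, TIPARP, SLC33A1 and METTL4. The falls included PPP1R10 (-0.75 ± 0.06), the phosphatase subunit that also fell most at 500 nM, KRCC1 (-0.68 ± 0.07) and TIPARP (-0.44 ± 0.05), a mono-ADP-ribosyltransferase. The rises included POLR2A (0.35 ± 0.05), RBM14 (0.39 ± 0.04), a paraspeckle protein gene, and C15orf39 (0.36 ± 0.05). These 6 genes passed without each of the 4 libraries in turn, and with the GC trend removed, and under mitochondrial scaling the 3 falls kept their direction without passing (-1.09, -1.02, -0.78) and the 3 rises were lost (-0.01, 0.04, 0.02). FOS (0.57 ± 0.14, adjusted p = 0.043) rose but did not pass without DMSO replicate 1 (0.35), THZ1 100 nM replicate 1 (0.48) or THZ1 100 nM replicate 2 (0.65). MYC (0.28 ± 0.05, adjusted p = 0.0069) rose, with -0.06 under mitochondrial scaling, but did not pass without DMSO replicate 1 (0.28), DMSO replicate 2 (0.28), THZ1 100 nM replicate 1 (0.30) or THZ1 100 nM replicate 2 (0.26). TUBD1 (-0.44 ± 0.07), a tubulin gene, fell but did not pass without THZ1 100 nM replicate 2 (-0.42). ZFP36 (0.40 ± 0.07), which encodes an mRNA decay factor, rose but did not pass without DMSO replicate 1 (0.34) or THZ1 100 nM replicate 2 (0.29). HEXIM1 (0.18 ± 0.05, adjusted p = 0.047) rose, with -0.17 under mitochondrial scaling, but did not pass without DMSO replicate 1 (0.22), DMSO replicate 2 (0.15), THZ1 100 nM replicate 1 (0.17) or THZ1 100 nM replicate 2 (0.18). JUN (0.22 ± 0.10) did not pass, but did without DMSO replicate 2 (0.36). MCL1 (-0.03 ± 0.04), SOX9 (-0.05 ± 0.04), KRT19 (-0.09 ± 0.04), CDKN1A (0.16 ± 0.05), MDM2 (0.06 ± 0.04), CDK7 (-0.05 ± 0.05), CDK12 (0.04 ± 0.05) and CDK13 (0.01 ± 0.05) did not pass. KRCC1 had no adjusted p under DESeq2. FOS did not pass under scaling by library totals (0.54), under limma-voom (0.58) or with the GC trend removed (0.52). FOS had no adjusted p under DESeq2. TUBD1 had no adjusted p under DESeq2. HEXIM1 did not pass under upper-quartile scaling (0.17), under scaling by library totals (0.15), with the filter at 1 CPM (0.18), under limma-voom (0.18) or with the GC trend removed (0.16). JUN passed without the low-count filter (0.23) and with the replicate block (0.21). KRT19 passed with the GC trend removed (-0.19). CDKN1A passed without the low-count filter (0.17) and in the fit of the 4 libraries (0.15). FOS (0.23), TUBD1 (-0.78) and ZFP36 (0.05) did not pass under mitochondrial scaling.

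In this comparison, edgeR called 128 genes higher and 125 lower, 4 and 4 by at least 2-fold, beside 3041 genes at an unadjusted p under 0.05. The calls fell to 4 and 10 without DMSO replicate 1, 32 and 64 without DMSO replicate 2, 13 and 14 without THZ1 100 nM replicate 1, and 3 and 6 without THZ1 100 nM replicate 2, and the split was 208 and 117 under DESeq2's size factors, 108 and 164 under upper-quartile scaling, 50 and 181 under scaling by library totals, 0 and 2 under mitochondrial scaling and 33 and 102 under removal of the GC trend. The changes also followed transcript GC content, with a Spearman correlation across 11555 genes of 0.52 in each THZ1 100 nM library against the same DMSO mean. Between the DMSO libraries it was -0.09. With the GC trend removed, 78 of the 253 genes kept their call and direction. The gene lists were not tested with that trend removed. Among 29 immediate-early genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.09 and -0.25 under mitochondrial scaling, camera adjusted p = 4.0e-06 and adjusted p = 0.31 with an estimated correlation. Among 17 glycolysis genes, none passed (0 and 0 adjusted over the list alone). Their median was 0.09 and -0.26 under mitochondrial scaling, camera adjusted p = 0.0052 and adjusted p = 0.66 with an estimated correlation. Among 13 mitochondrially encoded protein genes, none passed (0 and 0 adjusted over the list alone). Their median was 0.27, camera adjusted p = 0.0074 and adjusted p = 0.67 with an estimated correlation. Among 31 p53 target genes, 1 fell and 0 rose (1 and 3 adjusted over the list alone). Their median was 0.03, with medians of -0.002 under scaling by library totals and -0.32 under mitochondrial scaling, camera adjusted p = 0.19.

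Between the doses of THZ1, SOX9 (-1.48 ± 0.04), KRT19 (-1.37 ± 0.05) and MCL1 (-1.13 ± 0.04) were lower at 500 nM, as were the p53 targets CDKN1A (-1.22 ± 0.05) and MDM2 (-1.27 ± 0.05). MYC (-0.74 ± 0.05), JUN (-0.77 ± 0.10), CDK7 (-1.13 ± 0.06), CDK12 (-1.29 ± 0.05) and CDK13 (-0.82 ± 0.05) were also lower, and FOS (0.52 ± 0.13) and HEXIM1 (0.29 ± 0.05) were higher, of which HEXIM1 changed sign under mitochondrial scaling. Under mitochondrial scaling FOS (0.06) did not pass. The largest falls were in DCLRE1B (-3.44 ± 0.10), GTF2E1 (-3.34 ± 0.12), ZNF225 (-3.14 ± 0.10), E2F8 (-3.04 ± 0.11) and INTS5 (-3.04 ± 0.08), of which INTS5 encodes an Integrator subunit, and the largest rises in FAM166A (5.23 ± 0.18), BEST1 (2.84 ± 0.13), KRT15 (2.83 ± 0.07), MGC12916 (2.72 ± 0.08) and JUNB (2.25 ± 0.13). At 500 nM, 5393 genes were higher and 6656 lower than at 100 nM, 1440 and 2580 by at least 2-fold, a split that was 8466 and 4639 under upper-quartile scaling, 866 and 7046 under mitochondrial scaling and 7397 and 5380 under removal of the GC trend. Among 33 ribosome biogenesis genes, 29 were lower and 1 was higher (29 and 1 adjusted over the list alone). Their median was -0.94, camera adjusted p = 6.2e-14 and adjusted p = 0.030 with an estimated correlation. Among 18 YAP and TEAD target genes, 13 were lower and 3 were higher (13 and 3 adjusted over the list alone). Their median was -0.98, camera adjusted p = 7.8e-10 and adjusted p = 0.038 with an estimated correlation. Among 31 p53 target genes, 24 were lower and 0 were higher (24 and 0 adjusted over the list alone). Their median was -0.85, camera adjusted p = 1.2e-09 and adjusted p = 0.13 with an estimated correlation. Among 81 ribosomal protein genes, 77 were higher and 2 were lower (77 and 2 adjusted over the list alone). Their median was 0.44 and -0.02 under mitochondrial scaling, camera adjusted p = 9.7e-13 and adjusted p = 0.58 with an estimated correlation.

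Between the doses of actinomycin D, the p53 targets CDKN1A (-2.15 ± 0.06), MDM2 (-2.23 ± 0.05), SESN2 (-3.58 ± 0.08) and PPM1D (-3.51 ± 0.08) were lower at 150 ng/mL. MYC (-1.46 ± 0.06), MCL1 (-0.99 ± 0.04), SOX9 (-2.35 ± 0.05), KRT19 (-1.47 ± 0.05), CDK7 (-2.09 ± 0.07), CDK12 (-2.03 ± 0.06), CDK13 (-2.09 ± 0.06) and HEXIM1 (-0.32 ± 0.05) were lower too, while the AP-1 genes FOS (0.61 ± 0.13) and JUN (0.85 ± 0.10) were higher, of which FOS changed sign under mitochondrial scaling. HEXIM1 did not pass under upper-quartile scaling (-0.005). Under mitochondrial scaling JUN (0.04) did not pass. The other largest falls were in SPSB1 (-4.20 ± 0.10), RNF144B (-3.95 ± 0.08) and NGDN (-3.69 ± 0.12) and the largest rises in the mitochondrial RNAs MT-RNR1 (2.16 ± 0.17), MT-RNR2 (2.03 ± 0.21) and MT-TC (1.80 ± 0.10), the nuclear lncRNA NEAT1 (1.98 ± 0.16) and SHH (1.86 ± 0.07). At 150 ng/mL, 5660 genes were higher and 6369 lower than at 10 ng/mL, 854 and 3050 by at least 2-fold, a split that was 8295 and 4723 under upper-quartile scaling, 3737 and 7773 under scaling by library totals and 191 and 9561 under mitochondrial scaling. Among 31 p53 target genes, 26 were lower and 2 were higher (26 and 3 adjusted over the list alone). Their median was -1.48, camera adjusted p = 9.7e-20 and adjusted p = 0.025 with an estimated correlation. Among 33 ribosome biogenesis genes, 28 were lower and 4 were higher (28 and 4 adjusted over the list alone). Their median was -0.89, camera adjusted p = 8.7e-10 and adjusted p = 0.038 with an estimated correlation. Among 20 heat shock chaperones, 13 were lower and 4 were higher (13 and 4 adjusted over the list alone). Their median was -0.40, camera adjusted p = 0.0022 and adjusted p = 0.58 with an estimated correlation. Among 81 ribosomal protein genes, 79 were higher and 2 were lower (79 and 2 adjusted over the list alone). Their median was 0.66 and -0.15 under mitochondrial scaling, camera adjusted p = 2.4e-18 and adjusted p = 0.49 with an estimated correlation.

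Comparing the lower doses, the p53 targets CDKN1A (-1.26 ± 0.05), BTG2 (-1.33 ± 0.06) and MDM2 (-0.65 ± 0.04) were lower in THZ1 100 nM than in actinomycin D 10 ng/mL, as were HEXIM1 (-0.72 ± 0.05) and MCL1 (-0.39 ± 0.04). The genes LDLRAD4 (2.36 ± 0.08), GLI2 (1.96 ± 0.07), JAZF1 (1.87 ± 0.08), ZFPM2 (1.87 ± 0.08) and HDAC4 (1.80 ± 0.07), each spanning over 200 kb, were higher, and DOK3 (-1.71 ± 0.10), KRT15 (-1.65 ± 0.08) and MROH6 (-1.29 ± 0.11) lower. MYC (0.27 ± 0.05), SOX9 (0.35 ± 0.04), CDK12 (0.39 ± 0.05) and CDK13 (0.33 ± 0.05) were higher, and KRT19 (0.10 ± 0.04) and FOS (-0.15 ± 0.13) did not pass. KRT19 passed under limma-voom (0.10), in the fit of the 4 libraries (0.10) and with the GC trend removed (0.10). MDM2 (-0.81), MCL1 (-0.55), MYC (0.11), SOX9 (0.19), CDK12 (0.23) and CDK13 (0.17) did not pass under mitochondrial scaling. In THZ1 100 nM, 3637 genes were higher and 2574 lower, 259 and 406 by at least 2-fold, a split that was 2529 and 5260 under upper-quartile scaling, 194 and 339 under mitochondrial scaling and 2706 and 4957 under removal of the GC trend. The count of genes lower in THZ1 100 nM than in actinomycin D 10 ng/mL was 1544 without THZ1 100 nM replicate 2, 1457 without actinomycin D 10 ng/mL replicate 1 and 1715 without actinomycin D 10 ng/mL replicate 2. Among 31 p53 target genes, 27 were lower and 1 was higher (27 and 1 adjusted over the list alone). Their median was -0.40, camera adjusted p = 4.4e-24 and adjusted p = 0.038 with an estimated correlation. Among 18 YAP and TEAD target genes, 13 were higher and 2 were lower (13 and 2 adjusted over the list alone). Their median was 0.34, camera adjusted p = 1.1e-05 and adjusted p = 0.078 with an estimated correlation. Among 20 heat shock chaperones, 14 were lower and 3 were higher (14 and 3 adjusted over the list alone). Their median was -0.22, camera adjusted p = 2.7e-06 and adjusted p = 0.48 with an estimated correlation.

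Comparing the higher doses, MYC (0.98 ± 0.06), SOX9 (1.21 ± 0.05), KRT19 (0.19 ± 0.04), MDM2 (0.31 ± 0.05), CDK7 (1.10 ± 0.07), CDK12 (1.12 ± 0.06) and CDK13 (1.60 ± 0.06) were higher in THZ1 500 nM than in actinomycin D 150 ng/mL. JUN (-1.62 ± 0.10), MCL1 (-0.54 ± 0.04) and CDKN1A (-0.33 ± 0.05) were lower, with CDKN1A at -0.20 without actinomycin D 150 ng/mL replicate 2. FOS (-0.24 ± 0.12) and HEXIM1 (-0.11 ± 0.05) did not pass, but did without actinomycin D 150 ng/mL replicate 1 (-0.34 and -0.15). KRT19 did not pass under upper-quartile scaling (0.08). FOS passed under upper-quartile scaling (-0.35). HEXIM1 passed under upper-quartile scaling (-0.22), with the filter at 1 CPM (-0.13) and with the GC trend removed (-0.20). KRT19 (0.38), MDM2 (0.50), MCL1 (-0.35) and CDKN1A (-0.13) did not pass under mitochondrial scaling. The largest differences upward were in FAM166A (4.67 ± 0.18), BCOR (3.40 ± 0.08), MGC12916 (3.30 ± 0.09), FOXO1 (3.28 ± 0.12) and CNOT6L (3.27 ± 0.12), of which BCOR encodes a BCL6 corepressor and FOXO1 a forkhead factor. The largest downward were in E2F8 (-2.91 ± 0.11), MRPL38 (-2.56 ± 0.10), TRMT5 (-2.51 ± 0.10), PPP1R10 (-2.33 ± 0.09) and SMG8 (-2.17 ± 0.08). In THZ1 500 nM, 4738 genes were higher and 5473 lower, 1618 and 853 by at least 2-fold, a split that was 3959 and 6991 under upper-quartile scaling, 5936 and 3486 under scaling by library totals and 2957 and 700 under mitochondrial scaling. Among 38 transcription-cycle kinases and elongation regulators, 25 were higher and 7 were lower (25 and 9 adjusted over the list alone). Their median was 0.45, camera adjusted p = 2.0e-07 and adjusted p = 0.11 with an estimated correlation. Among 18 YAP and TEAD target genes, 10 were higher and 5 were lower (10 and 5 adjusted over the list alone). Their median was 0.36, camera adjusted p = 6.2e-05 and adjusted p = 0.098 with an estimated correlation. Among 20 snoRNA host genes, 18 were lower and 1 was higher (18 and 1 adjusted over the list alone). Their median was -0.48, camera adjusted p = 1.0e-06 and adjusted p = 0.25 with an estimated correlation. Among 81 ribosomal protein genes, 79 were lower and 0 were higher (81 and 0 adjusted over the list alone). Their median was -0.28, camera adjusted p = 2.0e-08 and adjusted p = 0.64 with an estimated correlation. Among 31 p53 target genes, 13 were higher and 13 were lower (13 and 13 adjusted over the list alone). Their median was -0.04 beside a mean of 0.09 and a camera direction of up, with medians of 0.09 under scaling by library totals and 0.15 under mitochondrial scaling, camera adjusted p = 0.91.

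With an estimated correlation, and with adjustment over all 224 tests of a list in a comparison, camera calls held for the p53 target genes in actinomycin D 10 ng/mL against DMSO and in its contrasts with actinomycin D 150 ng/mL and THZ1 100 nM, for the YAP and TEAD target genes in THZ1 500 nM against DMSO and against THZ1 100 nM, for the ribosome biogenesis genes in both dose contrasts and in no other test.

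**Figure D3:**
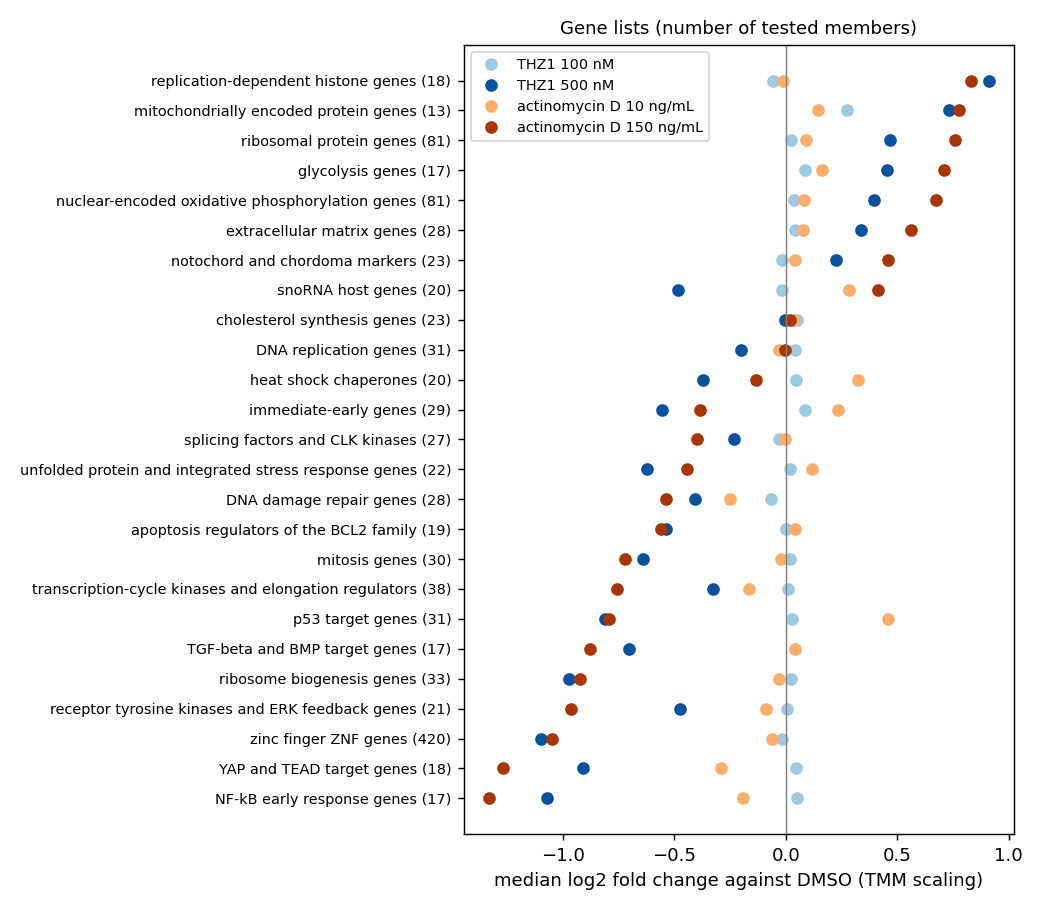
Median log2 fold change against DMSO of each gene list with at least 10 tested members, with 1 point per treatment on the TMM scale. Ribosomal protein genes stood at 0.47 in THZ1 500 nM and 0.76 in actinomycin D 150 ng/mL, and at -0.34 and -0.24 under mitochondrial scaling.

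Changes in THZ1 500 nM and actinomycin D 150 ng/mL overlapped. SOX9, KRT19, MCL1, CDKN1A, MDM2 and TBXT fell and FOS and HEXIM1 rose in both, while JUN fell in THZ1 500 nM and rose in actinomycin D 150 ng/mL. Under mitochondrial scaling, however, FOS passed in neither (0.29 and 0.33), HEXIM1 changed sign in both (-0.34 and -0.42) and JUN did not pass in actinomycin D 150 ng/mL (0.09), and JUN in THZ1 500 nM did not pass under upper-quartile scaling (-0.26) or in the fit of the 4 libraries (-0.49). Both comparisons used the same DMSO libraries, so values simulated for unchanged groups against those libraries are given beside the observed ones. Across genes, Pearson r was 0.70 (0.45 simulated) and the covariance 0.835 (0.0235 simulated). By calls, 4183 genes were higher in both (1830 for independent lists) and 5632 lower in both (2519), while 211 rose in THZ1 500 nM and fell in actinomycin D 150 ng/mL (2027 for independent lists) and 265 did the reverse (2274). For the 2 doses of actinomycin D, Pearson r was 0.51 (0.47 simulated) and the covariance 0.292 (0.0237 simulated), and 2050 genes were higher in both (1116 for independent lists) and 3112 lower in both (1454), while 778 rose at 10 ng/mL and fell at 150 ng/mL (1236 for independent lists) and 330 did the reverse (1312). For THZ1 100 nM and actinomycin D 10 ng/mL, Pearson r was 0.35 (0.50 simulated) and the covariance 0.0599 (0.0237 simulated), and 87 genes were higher in both (23.5 for independent lists) and 68 lower in both (27.0), while 16 rose in THZ1 100 nM and fell in actinomycin D 10 ng/mL (27.6 for independent lists) and 18 did the reverse (22.9). For the 2 doses of THZ1, Pearson r was 0.20 (0.50 simulated) and the covariance 0.0705 (0.0242 simulated). The simulated groups had no changes of their own, so an r below the simulated one does not by itself show unlike changes. The same limit holds for the share of genes with the same sign. By calls, 60 genes were higher in both (38.5 for independent lists) and 92 lower in both (46.8), while 49 rose at 100 nM and fell at 500 nM (47.9 for independent lists) and 12 did the reverse (37.6), and 56.7% of all genes had the same sign at both doses (66.5% simulated). Part of the excess may come from the shared controls. For THZ1 500 nM and actinomycin D 150 ng/mL, however, the simulated groups shared 0.3 calls on average beside the small simulated covariance. These values argue against shared controls as the main source of that overlap. A split that gave each comparison its own DMSO library was not made.

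**Figure D4:**
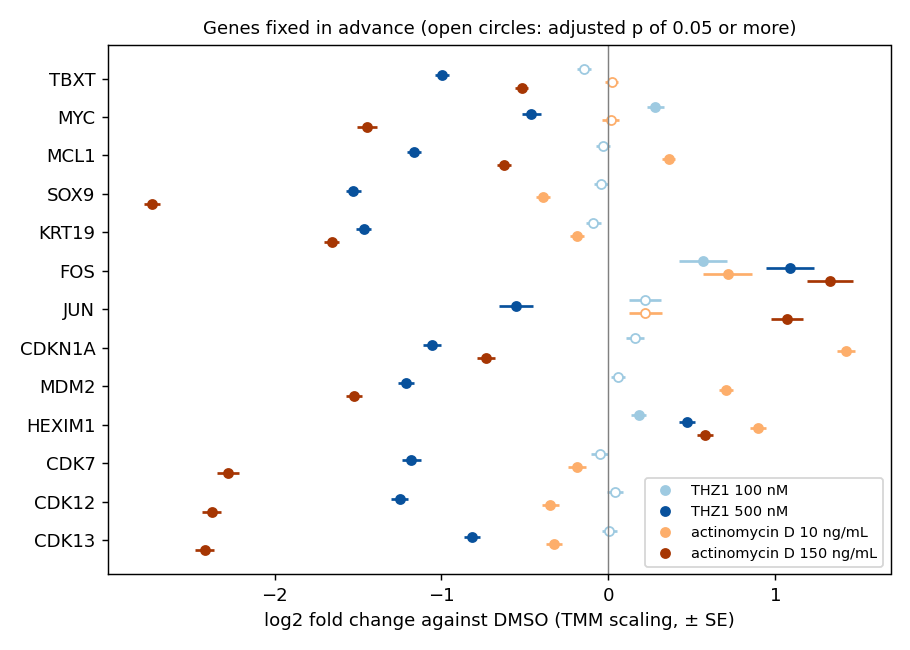
Log2 fold changes against DMSO, with SE bars, of 13 genes fixed in advance, with 1 color per treatment and open circles where the gene did not pass. CDKN1A stood at 1.42 in actinomycin D 10 ng/mL and -0.73 in actinomycin D 150 ng/mL.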

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

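The test on exon length, both tests on multimapping reads and the 12 definitions of a neighbour that varied distance and level were chosen after the result was seen. Some genes and lists changed in opposite directions at the 2 doses of a compound, with the difference itself tested as a contrast of doses. The values in brackets are for the lower dose, the higher dose and the difference. For actinomycin D these were MCL1 (0.36, -0.63 and -0.99, edgeR adjusted p = 4.0e-18), CDKN1A (1.42, -0.73 and -2.15, edgeR adjusted p = 1.7e-21) and MDM2 (0.70, -1.53 and -2.23, edgeR adjusted p = 2.6e-24), with each of the 2 libraries of a group on the stated side. Under mitochondrial scaling the rises of MCL1 (0.18) and MDM2 (0.52) at the lower dose did not pass. For THZ1 it was MYC (0.28, -0.46 and -0.74, edgeR adjusted p = 1.1e-12), where the rise at the lower dose did not pass when any 1 of the 4 libraries was left out (0.28 without DMSO replicate 1, 0.28 without DMSO replicate 2, 0.30 without THZ1 100 nM replicate 1 and 0.26 without THZ1 100 nM replicate 2) and was -0.063 under mitochondrial scaling.

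At the preset correlation, lists met the same condition in 4 cases. The median of the p53 target genes was 0.46 at actinomycin D 10 ng/mL (camera adjusted p = 4.4e-24), -0.79 at 150 ng/mL (camera adjusted p = 2.2e-05), and -1.48 between the doses (camera adjusted p = 9.7e-20, adjusted p = 0.025 with an estimated correlation). The median of the ribosome biogenesis genes was 0.022 at THZ1 100 nM (camera adjusted p = 0.041), or -0.0078 under scaling by library totals and -0.31 under mitochondrial scaling, -0.97 at 500 nM (camera adjusted p = 1.4e-12), and -0.94 between the doses (camera adjusted p = 6.2e-14, adjusted p = 0.030 with an estimated correlation). The median of the immediate-early genes was 0.089 at THZ1 100 nM (camera adjusted p = 4.0e-06), or -0.25 under mitochondrial scaling, -0.55 at 500 nM (camera adjusted p = 0.018), and -0.74 between the doses (camera adjusted p = 0.0016, adjusted p = 0.49 with an estimated correlation). The median of the DNA replication genes was 0.044 at THZ1 100 nM (camera adjusted p = 0.029), or -0.30 under mitochondrial scaling, -0.20 at 500 nM (camera adjusted p = 0.011), or 0.10 under upper-quartile scaling, and -0.21 between the doses (camera adjusted p = 0.0028, adjusted p = 0.59 with an estimated correlation), or 0.098 under upper-quartile scaling. With an estimated correlation, the p53 target genes at actinomycin D 10 ng/mL passed against DMSO (adjusted p = 0.038) but those at 150 ng/mL did not (adjusted p = 0.18), so their opposite directions rest on the preset correlation, and none of the 3 lists did so at either dose of THZ1.

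Multimapping reads, which no comparison of genes uses, made up 18.8 ± 0.343% of all reads (SD, n = 2) in THZ1 500 nM, above the 7.59% in DMSO, 7.39% in THZ1 100 nM, 7.72% in actinomycin D 10 ng/mL and 9.22% in actinomycin D 150 ng/mL. More mRNA of the ribosomal protein and mitochondrially encoded genes, families with many copies, is argued against as the cause, because actinomycin D 150 ng/mL, in which the medians of these 2 families rose at least as much, gained 1.62 percentage points against 11.3 in THZ1 500 nM, a ratio of 0.144. More reads from multi-copy small structured RNAs stays open. Their uniquely counted reads, scaled to library size, were at a ratio to DMSO of 1.45, between the 1.2 and 2 set as limits, with 1.59 for 7SK, 1.42 for 7SL, 1.43 for spliceosomal and 1.00 for 5S ribosomal RNA copies. Sequences of the multimapping reads were not in the files, and other sources, such as the replication-dependent histone genes, were not tested.

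Genes at least 2-fold higher in THZ1 500 nM than in DMSO more often had a same-strand gene at 5 times their DMSO level or more ending within 5 kb upstream, 194 of the 1325 with an annotated position (14.6% against 9.52% in expression-matched draws, a ratio of 1.54, permutation p = 0.0001, the smallest that 10000 draws can give). The ratio lay just above the limit of 1.5 and from 1.27 to 2.28 over the 12 definitions, 6 of which reached it, and it was 2.46 in actinomycin D 150 ng/mL and 3.26 in actinomycin D 10 ng/mL. Reads running on from such a neighbour may account for a small part of these rises, and the excess is shared with actinomycin D. The draws were matched on DMSO expression alone, not on gene span or on how densely genes lie. They therefore cannot show that the excess comes from such reads. Overlap with a more abundant gene on the other strand had a ratio of 1.28 (36.5% against 28.4%, and 0.983 in actinomycin D 150 ng/mL), below the limit although permutation p = 0.0001 was again the smallest possible, so reads of such genes cannot be told apart from changes of the genes themselves. No biological explanation of these rises was tested.

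Longer genes were lower in actinomycin D 10 ng/mL than in DMSO. A bias by GC content is argued against as the whole cause, since the Spearman correlation with gene span was -0.58 given GC content (-0.59 and -0.56 in the 2 libraries). Given exon length the correlation with span was -0.57 (-0.57 and -0.54), past the limit set against a bias by mature transcript length. Exon length here merges the exons of all annotated transcripts of a gene, however. It can differ from the length of the mature transcript, so this value does not exclude that bias. Given exon length, GC content and DMSO expression together, the correlation with span was -0.52 (-0.53 and -0.50 in the 2 libraries). This is what slowed transcription along long genes might give, a hypothesis that rests on the same data and that any other cause linked to gene length would meet too.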

How the results depend on the processing

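Leaving out the mitochondrial genes and removing each library's trend with GC content were chosen after the results were seen. Scaling on spike-in sequences gave no value, since the table holds none. Mitochondrial genes left out, limma-voom, a filter at 1 CPM in 2 libraries and the replicate block changed no count of genes by more than 1.5 times. Correlations of replicate differences between groups lay between -0.14 and 0.21, which does not settle whether the replicate numbers pair the libraries. With the block, 176 genes were higher and 176 lower in THZ1 100 nM than in DMSO (128 and 125 without it). Values below are counts of genes past the threshold, then the value as reported in brackets.

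Scaling on the mitochondrially encoded protein genes gave 0 higher and 2 lower in THZ1 100 nM against DMSO (128 and 125), 581 higher and 10655 lower in THZ1 500 nM against DMSO (5378 and 6684), 124 higher and 869 lower in actinomycin D 10 ng/mL against DMSO (3281 and 3857), 306 higher and 11096 lower in actinomycin D 150 ng/mL against DMSO (6081 and 6735), 866 higher in THZ1 500 nM against THZ1 100 nM (5393), 191 higher and 9561 lower in actinomycin D 150 ng/mL against actinomycin D 10 ng/mL (5660 and 6369), 194 higher and 339 lower in THZ1 100 nM against actinomycin D 10 ng/mL (3637 and 2574) and 2957 higher and 700 lower in THZ1 500 nM against actinomycin D 150 ng/mL (4738 and 5473). Upper-quartile factors gave 8232 higher in THZ1 500 nM against DMSO (5378), 5240 higher in actinomycin D 10 ng/mL against DMSO (3281), 8466 higher in THZ1 500 nM against THZ1 100 nM (5393) and 5260 lower in THZ1 100 nM against actinomycin D 10 ng/mL (2574). With library totals alone there were 50 higher in THZ1 100 nM against DMSO (128), 3737 higher in actinomycin D 150 ng/mL against actinomycin D 10 ng/mL (5660) and 3486 lower in THZ1 500 nM against actinomycin D 150 ng/mL (5473). DESeq2's size factors in edgeR gave 208 higher in THZ1 100 nM against DMSO (128). With the GC trend removed there were 33 higher in THZ1 100 nM against DMSO (128) and 4957 lower in THZ1 100 nM against actinomycin D 10 ng/mL (2574). Changes of scale other than the GC trend shift every fold change of a comparison by about the same amount.

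Without the low-count filter there were 311 higher and 190 lower in THZ1 100 nM against DMSO (128 and 125). DESeq2 called 62 lower in THZ1 100 nM against DMSO (125). A fit of only the 4 libraries compared gave 623 higher and 541 lower in THZ1 100 nM against DMSO (128 and 125). At an adjusted p under 0.01 there were 12 higher and 18 lower in THZ1 100 nM against DMSO (128 and 125) and 1602 lower in THZ1 100 nM against actinomycin D 10 ng/mL (2574). At 2-fold or more there were 4 higher and 4 lower in THZ1 100 nM against DMSO (128 and 125), 1355 higher and 2606 lower in THZ1 500 nM against DMSO (5378 and 6684), 364 higher and 272 lower in actinomycin D 10 ng/mL against DMSO (3281 and 3857), 1587 higher and 3530 lower in actinomycin D 150 ng/mL against DMSO (6081 and 6735), 1440 higher and 2580 lower in THZ1 500 nM against THZ1 100 nM (5393 and 6656), 854 higher and 3050 lower in actinomycin D 150 ng/mL against actinomycin D 10 ng/mL (5660 and 6369), 259 higher and 406 lower in THZ1 100 nM against actinomycin D 10 ng/mL (3637 and 2574) and 1618 higher and 853 lower in THZ1 500 nM against actinomycin D 150 ng/mL (4738 and 5473). DESeq2's independent filtering left 10741 genes without an adjusted p in THZ1 100 nM against DMSO, 1733 in actinomycin D 10 ng/mL against DMSO and 2426 in THZ1 100 nM against actinomycin D 10 ng/mL.

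Brachyury in THZ1 100 nM against DMSO, which did not pass, passed with -0.16 under upper-quartile factors, -0.18 under library totals, -0.15 under the filter at 1 CPM, -0.14 under DESeq2, -0.15 under limma-voom, -0.15 under the fit of 4 libraries and -0.23 under removal of the GC trend. In actinomycin D 10 ng/mL against DMSO it passed with 0.11 under upper-quartile factors. Under mitochondrial scaling it no longer passed, with -0.32 in THZ1 100 nM against actinomycin D 10 ng/mL and -0.29 in THZ1 500 nM against actinomycin D 150 ng/mL. The causes of these differences were not tested. Of the genes named in the report, these changed sign under mitochondrial scaling: in THZ1 500 nM against DMSO, ATP5F1B -0.32, EGFL7 -0.17, GAPDH -0.24, HEXIM1 -0.34, NDUFB7 -0.24, PKM -0.27, RPL12 -0.25, RPL37 -0.21, RPS2 -0.20, THY1 -0.24, TIMP1 -0.12 and TIMP2 -0.18, in actinomycin D 150 ng/mL against DMSO, COX4I1 -0.18, HEXIM1 -0.42, NDUFV1 -0.15, RPL12 -0.043, RPL37 -0.0083 and SNHG1 -0.46, in actinomycin D 150 ng/mL against actinomycin D 10 ng/mL, FOS -0.17, in THZ1 100 nM against DMSO, HEXIM1 -0.17, MYC -0.063 and POLR2A -0.0078, and in THZ1 500 nM against THZ1 100 nM, HEXIM1 -0.17. With the GC trend removed, CDK7 0.011 in actinomycin D 10 ng/mL against DMSO changed sign. Under mitochondrial scaling 44 more values for named genes kept their direction but no longer passed, and 6 under upper-quartile factors.

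Leaving out 1 library at a time left an arm with 1 library, which edgeR takes to vary like the other groups. The counts ranged over 3 to 32 higher (128) and 6 to 64 lower (125) in THZ1 100 nM against DMSO, 2110 to 2468 higher (3281) in actinomycin D 10 ng/mL against DMSO and 1457 to 1750 lower (2574) in THZ1 100 nM against actinomycin D 10 ng/mL. Brachyury in THZ1 100 nM against actinomycin D 10 ng/mL ranged from -0.19 to -0.13 (-0.17). Camera with an estimated correlation in place of the preset 0.01 ended 100 list calls and left the other 124 list tests on the same side of the threshold.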

Other observations

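The GC trend below was looked for after the results were seen. Mitochondrial ribosomal RNA made up 0.485 ± 0.123% of gene counts (SD, n = 2) in DMSO, 0.574% in THZ1 100 nM, 0.752% in THZ1 500 nM, 0.538% in actinomycin D 10 ng/mL and 1.90 ± 0.101% in actinomycin D 150 ng/mL.

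Changes against DMSO followed transcript GC content across 11555 genes in all 4 comparisons, with Spearman correlations in the 2 libraries of 0.52 and 0.52 for THZ1 100 nM, 0.17 and 0.18 for THZ1 500 nM, 0.48 and 0.41 for actinomycin D 10 ng/mL and 0.25 and 0.31 for actinomycin D 150 ng/mL. Each library was set against the mean of the same 2 DMSO libraries, so the 4 comparisons are not independent. A GC trend in the DMSO libraries alone would enter all of them. Between replicate libraries it was -0.095 in DMSO and -0.034 in THZ1 100 nM. Replicate counts varied beyond counting noise, with chi-square over degrees of freedom from 1.91 in THZ1 500 nM to 10.8 in DMSO. By gene the order differed. Among genes averaging at least 10 CPM, the median absolute log2 difference between replicates was largest in actinomycin D 150 ng/mL (0.097, beside 0.048 in DMSO).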
